A study of Mus musculus with 28 samples.

How the data were processed

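RNA-seq was deposited for 28 libraries of mouse bone marrow-derived dendritic cells grown with GM-CSF and IL-4, per the labels. The cells came from 4 genotypes: wild type (WT), RelB knockout (RelBko), knockout of the type I interferon receptor IFNAR (IFNARko) and the double knockout (IFNARko;RelBko). Each genotype gave 1 control library and 1 library at each of 1, 3 and 8 h after CpG DNA (ODN 1668, a TLR9 ligand) and after high molecular weight Poly(I:C), a double-stranded RNA mimic. The labels state the Poly(I:C) dose as 10 ng/mL in the sample titles and 10 µg/mL in the protocol, so the dose is uncertain. The control libraries are labelled 1 h only, so every later time point was set against a 1 h control. Libraries were stranded mRNA libraries sequenced from a single end, per the labels.

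The authors deposited 2 sheets of normalised values, and the submitters' processing notes name cutadapt, edgeR and the mm10 build without versions. The aligner, the counting tool and the annotation were not given in the sources used here. The deposited values (recorded as signal, since no unit is named) are read counts scaled to a library total of 1000000 (CPM) with 1 added: the lowest value is 1, and in the CpG sheet the values less 1 sum to 1000000 in each column. The CPM scaling used the library total and no further factor. Whole reads were recovered from the values, and 100% of them lay within 0.001 read of a whole number. The CpG sheet has 27178 entries, of which 2161 carry no gene name, and the Poly(I:C) sheet has 25019, of which 2 carry none. The unnamed entries hold 0.073% to 0.12% of each library in the CpG sheet. The Poly(I:C) sheet lacks most of them, and its values less 1 sum to 998750 to 999250. The 4 control columns hold identical values in both sheets, so the sheets share a scale. A further 11 symbols on more than 1 line were left out, which left 24995 genes. Depth ran from 3269933 reads (IFNARko, CpG 8 h) to 42227938 reads (WT, CpG 8 h), with 14389 to 18557 genes holding at least 1 read. The values of a gene near 1 CPM therefore rest on few reads in the shallowest libraries, and reads are not independent molecules.

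Tests were run with limma 3.58.1 (lmFit, contrasts and eBayes with trend and robust) in R 4.3.3 with statmod 1.5.0, on log2 of CPM plus a pseudocount of 1. A gene was tested when its CPM was at least 1 in at least 3 libraries of the fit. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. All tests were two-sided, and errors are standard errors (SE) of the limma estimate. Because each group holds 1 library, no group has replicates, and each fit takes its spread from time points, genotypes or stimuli treated as repeats. The labels do not say whether libraries come from separate cultures or mice, and the p-values then measure only the spread between these samples.

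Genotype comparisons used the 12 stimulated libraries of a stimulus, with time as a term and genotype as 4 levels, so each estimate averages 3 times and its spread is that of genotype differences between times. Responses used the 4 control and 12 stimulated libraries of a stimulus, with genotype as a block. A fit of the 24 stimulated libraries gave the RelB effect at each time over both stimuli, and a second fit gave the difference of that effect between stimuli. A fit of all 28 libraries gave the RelB effect in the control libraries. Genes induced at least 2-fold in WT at their highest time were classed as IFNAR-dependent where IFNARko reached at most 0.5 of WT and as IFNAR-independent above 0.75 of WT, and each class was made in the libraries of 1 stimulus and tested in the other. These comparisons, the filter, 28 gene lists and the rule for naming genes were fixed before the data were examined. A further fit of all 28 libraries, chosen after the data were seen, compared the change from control to the mean of 3 and 8 h between RelB states and between IFNAR states.

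Of the 28 lists, 26 were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists of type I and III interferons and of erythroid markers had fewer than 3 tested members. Set p-values were adjusted over lists and contrasts within a family of fits. Genes were named by rule: Relb and Ifnar1 in every library; per genotype comparison, the 10 largest rises and 10 largest falls among called genes with 1 sign at all 3 times and a mean of at least 5 CPM; up to 4 members of each discussed list with the lowest adjusted p; per response, the 5 largest rises and 3 largest falls; per interaction, the 5 lowest adjusted p of each sign; and Ifnb1, Ifna4, Il12b, Il6, Tnf, Cxcl10, Ccr7 and Nfkb2 throughout. The fit chosen after the data were seen lies outside the rule. Besides list members and the fixed genes, its named genes came from its 10 largest called rises and 10 largest called falls at a mean of at least 5 CPM. Coordinates are from GENCODE M21 (GRCm38, the mm10 assembly). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

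The fits were tested on simulated data. Reads were drawn for each library independently around a mean per gene, at the real depths and with a dispersion of 0.01. Changes were planted in 200 genes. The shares below therefore do not cover libraries of a genotype that share a culture or animal. For RelBko against WT after CpG, 47.0% of planted log2 changes of 0.5, 94.0% of those of 1 and 98.5% of those of 2 were called, and 3.61% of the calls were false. For the CpG response by IFNAR the shares were 13.6%, 65.7% and 95.5%, with 2.50% false. The false share was highest, at 10.4%, for RelBko against WT after Poly(I:C), above the 5% aimed at. Alternatives changed the pseudocount, the filter, the scaling, the eBayes settings, the libraries used and the set test. Limma voom on the recovered reads and the removal of shallow libraries, of sex-linked genes and of genes near the targeted loci were added after the data were seen. A count-based method with its own size factors, named beforehand for raw counts only, was not run on the recovered reads.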

Results

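The 28 libraries measured polyadenylated RNA in dendritic cells cultured from mouse bone marrow. Each of the 4 genotypes held 7 libraries, 1 control and 3 times after each of 2 stimuli, so each group had 1 library and no group had replicates. RelB is a subunit of the transcription factor NF-kB, and IFNAR is the receptor through which type I interferons signal. Depth was 3269933 to 42227938 reads, and the double knockout CpG 8 h library held 3814916. The labels frame the series as a study of RelB in gene regulation with and without interferon signalling. Values are CPM, changes are on the log2 scale with the SE of the limma fit, and p-values are adjusted over all genes tested unless said otherwise.

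Transcripts of both targeted genes were still detected in the knockout libraries, at lower levels. Relb (chromosome 7, 19606217 to 19629438) stood at 93.9 CPM in WT control cells and 72.4 CPM in RelBko control cells. Over the 7 conditions the RelBko value was 0.675 to 0.998 of the WT value, and the double knockout value was 0.613 to 0.851 of the IFNARko value, lower in 7 of 7 conditions in both. Ifnar1 (chromosome 16, 91485238 to 91507441) stood at 109.2 CPM in WT and 82.4 CPM in IFNARko control cells. It was 0.478 to 0.772 of WT in IFNARko and 0.463 to 0.802 of RelBko in the double knockout, again lower in 7 of 7 conditions. These are values for whole genes, so they check the genotype labels only weakly. Transcripts of the sex chromosomes differed between genotypes: Xist, the RNA that silences an X chromosome in female cells, was 445 to 831.5 CPM in WT and 712.9 to 1042 CPM in the double knockout. It stayed below 1 CPM in RelBko and IFNARko, where 4 Y-linked genes summed to 239 to 298 CPM and 221 to 263 CPM. Every comparison of RelBko with WT, of the double knockout with IFNARko and of IFNARko with WT therefore also compares libraries that differ in these transcripts.

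**Figure D1:**
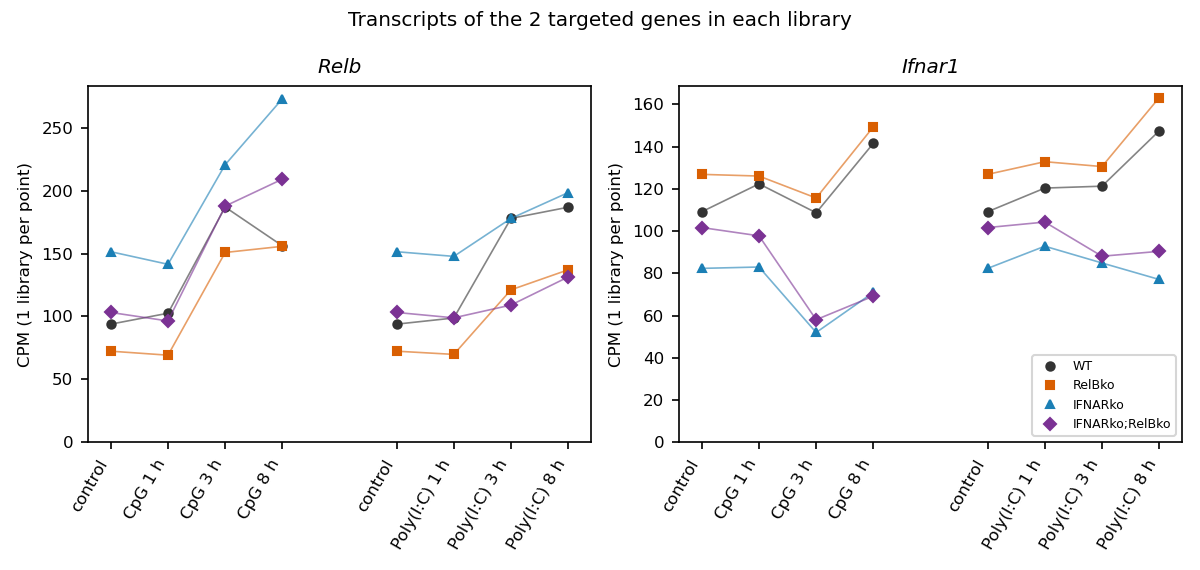
CPM of Relb (left) and Ifnar1 (right) by condition, 1 point per library, coloured by genotype, with the control library drawn at the left of each stimulus series. Relb was lower in RelBko than in WT and Ifnar1 lower in IFNARko than in WT in 7 of 7 conditions, and both remained detected.

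The CpG response was compared with control cells across the 4 genotypes. All control libraries are labelled 1 h, so the changes at 3 and 8 h may include changes with time in culture. At 1 h the inflammatory cytokine Tnf rose by 4.59 ± 0.25 (adjusted p 1.2e-05), from 9.75 to 339.9 CPM in WT. The NF-kB regulator Nfkbiz rose by 4.43 ± 0.28, the cytokine signalling inhibitor Socs3 by 3.45 ± 0.25, the co-stimulatory ligand Tnfsf9 by 3.27 ± 0.19 and the immediate early factor Egr1 by 3.11 ± 0.45. By 3 h Il12b, the shared chain of IL-12 and IL-23, had risen by 6.25 ± 0.51 (adjusted p 1.1e-05), Il1b by 5.88 ± 0.25 and the neutrophil chemokine Cxcl2 by 5.29 ± 0.28, while the transcription factor Klf4 fell by 2.62 ± 0.18. At 8 h the scavenger receptor Marco rose by 7.18 ± 0.32 (adjusted p 8.2e-09), the chemokine Cxcl5 by 6.72 ± 0.65 and Il12b by 6.54 ± 0.51, whereas Emp1 fell by 3.46 ± 0.23. Il6 rose by 4.51 at 3 h, and Cxcl10, a chemokine that draws T cells, by 2.58.

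Of 28 tested inflammatory cytokine genes, 4 rose at 1 h, 19 at 3 h and 23 at 8 h, with no falls at any of these times (12, 20 and 23 adjusted over the list alone). The camera adjusted p was 1.5e-22, 3.0e-18 and 2.0e-16, and the adjusted p = 0.038 with an estimated correlation at each time. At 1 h 10 of 29 immediate early genes rose and none fell (16 and 3 adjusted over the list alone), among them Ier2 (1.15 ± 0.13) and a pair of genes that restrain inflammatory signalling, Dusp1 (1.21 ± 0.11) and Zfp36 (1.32 ± 0.14), and the adjusted p = 0.02 with an estimated correlation. NF-kB subunits and feedback genes rose in 6, 23 and 24 of 27 cases at 1, 3 and 8 h and fell in 0, 2 and 1 (7, 23 and 24 up and 0, 2 and 1 down adjusted over the list alone; adjusted p = 0.038 with an estimated correlation at each time), and Nfkbia, the inhibitor IkBα, had risen by 1.43 ± 0.07 at 1 h. At 8 h 28 of 37 dendritic cell maturation and migration genes rose and 7 fell (the same counts adjusted over the list alone; adjusted p = 0.038 with an estimated correlation), the rises including Fscn1 (2.25 ± 0.12), Cd80 (1.96 ± 0.12) and the lymph node homing receptor Ccr7 (0.84). Of 71 interferon-stimulated genes 26 rose and 3 fell at 8 h (22 and 2 adjusted over the list alone, and adjusted p = 0.78 with an estimated correlation). Their summed level at 8 h was 19450 CPM in WT and 19430 CPM in RelBko. It was 4850 CPM in IFNARko and 3235 CPM in the double knockout, and the fit counts this difference as spread. At that time 30 of 32 proliferation genes fell, with Pcna falling by 0.92 ± 0.08 and Mcm7 by 1.01 ± 0.12, and 1 rose (the same counts adjusted over the list alone; camera adjusted p 2.2e-05, adjusted p = 0.72 with an estimated correlation).

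Limma called 64 genes at 1 h (49 up, 15 down), 5574 at 3 h (1558 up, 4016 down) and 6817 at 8 h (1925 up, 4892 down). Median-ratio scaling moved the median of all genes by 0.13 at 3 h and 0.15 at 8 h and gave 2279 up and 2324 down and 2968 up and 3118 down, so the excess of falls depends on the scaling, and quantile normalisation gave 55 up and 29 down at 1 h. The 1 h count was 30 without RelBko, 36 without IFNARko and 109 without the libraries of lowest depth.

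The Poly(I:C) response was compared with control cells in the same way. Each change is therefore an average over genotypes with and without IFNAR. At 3 h the antiviral enzyme Oas1b rose by 1.87 ± 0.57 (adjusted p 0.04), the RNA sensor Ifih1 by 1.51 ± 0.38 (adjusted p 0.018) and the formyl peptide receptor Fpr2 by 1.49 ± 0.19. At 8 h Marco rose by 2.73 ± 0.30 (adjusted p 1e-05), the chemokine precursor Ppbp by 2.64 ± 0.41 and the amino acid transporter Slc16a10 by 2.39 ± 0.18, while Emp1 fell by 2.81 ± 0.12 and the IL-1 decoy receptor Il1r2 by 2.59 ± 0.21. Il12b rose by 1.32 at 3 h (adjusted p 0.0024), Il6 by 1.18, and Ccr7 by 0.60 at 8 h. Tnf was not called at any time, with estimates of 1.16, 0.86 and 0.81. Ifnb1, the gene of interferon beta, did not exceed 1.97 CPM in any library, and Ifna4 did not pass the filter.

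At 8 h 32 of 71 interferon-stimulated genes rose and none fell (the same counts adjusted over the list alone), among them Epsti1 (1.16 ± 0.12), Ddx60 (1.91 ± 0.31) and Helz2 (1.58 ± 0.30). At 3 h 8 rose, and 0 were called adjusted over the list alone. The camera adjusted p was 2.0e-06 at 3 h and 3.5e-10 at 8 h, and the adjusted p = 0.83 with an estimated correlation at both times. Dendritic cell maturation genes rose in 19 and 21 of 37 cases and fell in 1 and 5, with Serpinb6b up by 1.11 ± 0.08 at 8 h (20 up and 2 down, and 21 up and 5 down, adjusted over the list alone; adjusted p = 0.74 with an estimated correlation at both times). Inflammatory cytokine genes rose in 7 and 8 of 24 cases and fell in 0 and 2, with the same counts adjusted over the list alone and an adjusted p = 0.79 and 0.81 with an estimated correlation. Macrophage and monocyte markers rose in 10 of 22 cases at 8 h and fell in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.74 with an estimated correlation), with the growth factor receptor Csf1r up by 0.94 ± 0.08 and the macrophage scavenger protein Cd5l by 1.80 ± 0.17.

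Limma called 42 genes at 1 h (41 up, 1 down), 2991 at 3 h (1758 up, 1233 down) and 5457 at 8 h (2397 up, 3060 down). The 1 h calls were led by Ptger1, a prostaglandin receptor (1.64 ± 0.28), and by 4 predicted genes, and the fall was Bri3 (-0.43 ± 0.07). That count was 7 with median-ratio scaling (6 up, 1 down), 26 with quantile normalisation, 19 with voom and 0 with plain eBayes, and leaving out a genotype gave 0 (RelBko), 6 (IFNARko), 17 (double knockout) or 25 (WT). Without RelBko the counts at 3 and 8 h were 1184 and 3442, and median-ratio scaling gave 1542 up and 1631 down at 3 h.

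**Figure D2:**
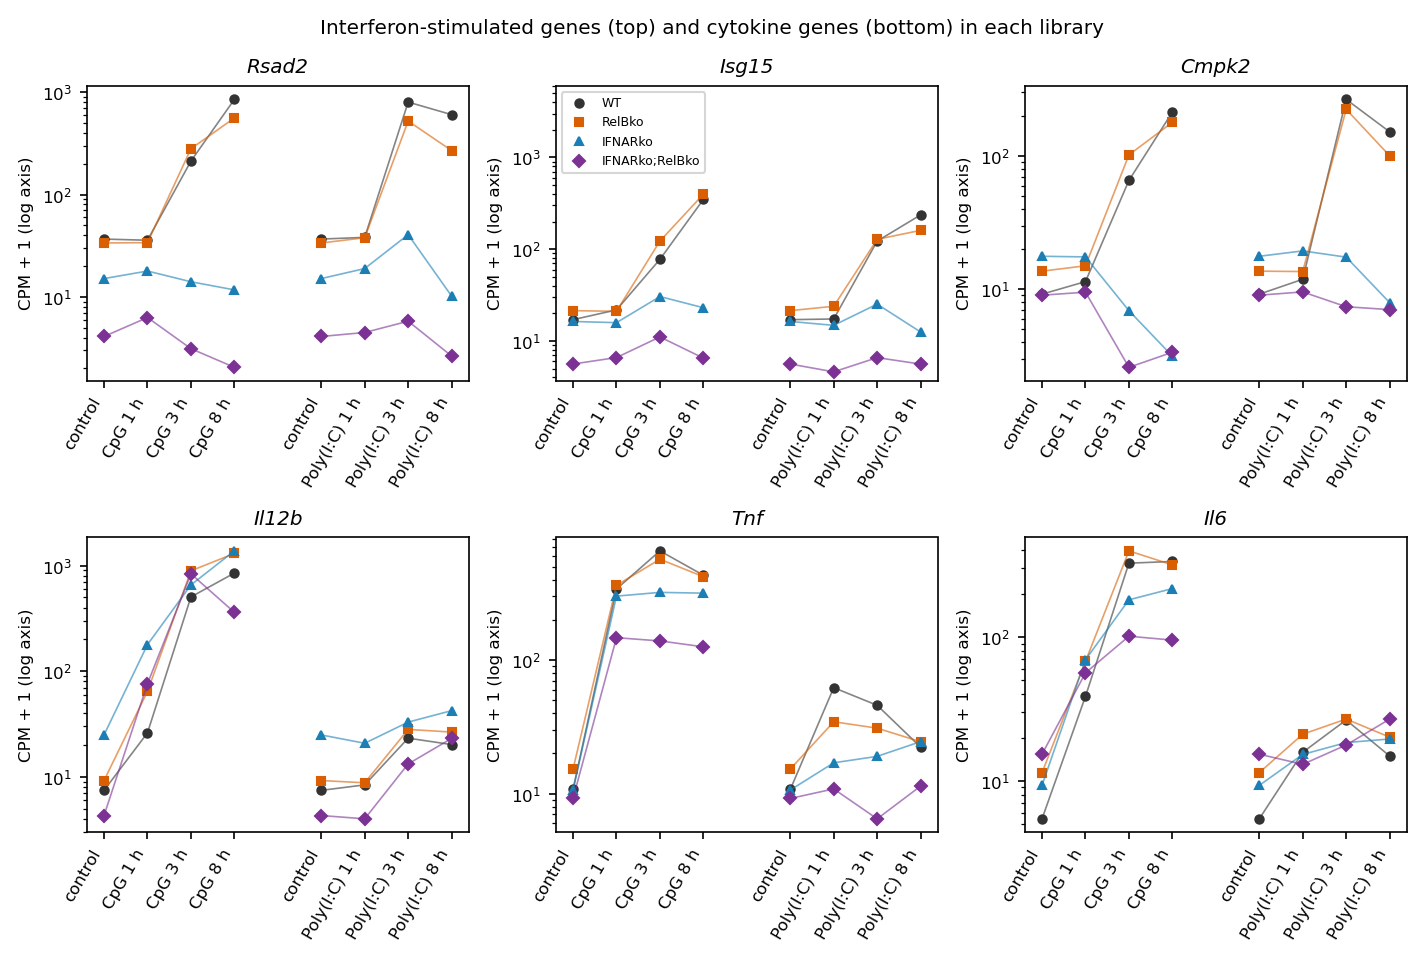
CPM plus 1 (log axis) of 3 interferon-stimulated genes (top) and 3 cytokine genes (bottom) by condition, 1 point per library, coloured by genotype, with the control library drawn at the left of each stimulus series. Rsad2 reached 848.7 CPM in WT at CpG 8 h against 10.7 CPM in IFNARko, while Tnf rose within 1 h of CpG in all 4 genotypes.

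The part that IFNAR takes in these responses was tested as the difference in the change from control to the mean of 3 and 8 h between IFNAR-null and IFNAR-intact cells, a fit chosen after the data were seen. Less and more refer here to the signed change from control. The nucleotide kinase gene Cmpk2 responded less without IFNAR by -5.27 ± 0.55 after CpG (adjusted p 0.0022), Ifit2 and Ifit3, which bind viral RNA, by -5.03 ± 0.72 and -4.18 ± 0.40, and the antiviral enzyme Rsad2 (chromosome 12, 26442746 to 26456452) by -4.01 ± 0.30. After Poly(I:C) the same differences were -4.41 ± 0.55 for Cmpk2, -4.57 ± 0.72 for Ifit2, -4.27 ± 0.40 for Ifit3 and -3.68 ± 0.30 for Rsad2. In WT cells Rsad2 went from 35.7 CPM to 848.7 CPM at CpG 8 h and 798.9 CPM at Poly(I:C) 3 h. In IFNARko cells it lay between 9.17 and 39.6 CPM throughout, and in the double knockout it did not exceed 5.28 CPM. Il6 responded less to CpG by -1.89 ± 0.24 (adjusted p 0.00072), and Cxcl10 by -2.03 ± 0.40 after CpG (adjusted p 0.016) and -2.96 ± 0.40 after Poly(I:C) (adjusted p 0.0022).

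Of 71 interferon-stimulated genes, 64 responded less to CpG and 62 less to Poly(I:C) without IFNAR, and none responded more (67 and 67 lower adjusted over the list alone). The camera adjusted p was 1.7e-78 and 1.1e-82, and the adjusted p = 0.25 with an estimated correlation in both. GBP and IRG family GTPases, which attack intracellular pathogens, responded less in 12 and 8 of 17 cases (14 lower, and 12 lower with 1 higher, adjusted over the list alone), including Igtp (-1.66 ± 0.17 after CpG) and Irgm2 (-1.93 ± 0.20 after CpG). The adjusted p = 0.38 and 0.39 with an estimated correlation. Cell cycle genes went the other way: the signed change was higher without IFNAR for 9 of 32 proliferation genes after CpG and 9 after Poly(I:C) (12 and 21 adjusted over the list alone; adjusted p = 0.39 and 0.38 with an estimated correlation), with Ube2c higher by 1.16 ± 0.19 and 1.46 ± 0.19. The summed level of the list fell from control to CpG 8 h in all 4 genotypes, from 773.9 to 402.5 CPM in WT, 846.6 to 475.8 CPM in RelBko, 1922 to 1135 CPM in IFNARko and 1991 to 1638 CPM in the double knockout. At Poly(I:C) 8 h it had fallen to 506.7, 662.5 and 1705 CPM in the first 3 and risen to 2507 CPM in the double knockout. The calls were 812 for CpG (424 up, 388 down) and 564 for Poly(I:C) (234 up, 330 down), and they were 513 and 356 without a filter and 341 and 245 with plain eBayes. Without the 2 shallowest libraries the Poly(I:C) count was 871. Median-ratio scaling gave 270 up and 552 down for CpG.

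Far fewer responses differed with RelB. These differences are averaged over the IFNAR backgrounds and were not tested within each. After CpG, Il6 responded less without RelB by -1.35 ± 0.24 (adjusted p 0.039) and the fungal receptor Clec4e by -1.24 ± 0.20. The level of Il6 after CpG was not called as different between RelBko and WT. The signed change of the transcription factor Prdm1 was lower by -0.75 ± 0.16, and the inhibitory ligand gene Cd200 responded more by 1.12 ± 0.17 (adjusted p 0.011). After Poly(I:C), Irg1, which makes itaconate, responded less by -1.25 ± 0.14 (adjusted p 0.0055), from 250.3 to 1752 CPM at 3 h in WT and from 279.8 to 965.8 CPM in RelBko. The acyl-CoA synthetase Acsl1 responded less by -0.83 ± 0.09, and so did the redox genes Srxn1 (-0.68 ± 0.11), Gclm (-0.63 ± 0.11), Txnrd1 (-0.54 ± 0.10) and Prdx1 (-0.54 ± 0.10), a grouping seen after the values and not tested as a set. Of 71 interferon-stimulated genes 2 responded more to CpG and none less (the same adjusted over the list alone). For Poly(I:C) limma called 0 of them over all genes, 1 as higher adjusted over the list alone and 4 at an unadjusted p under 0.05, and voom called 1 higher and 3 lower. Camera gave an adjusted p of 0.38 and 0.32 for this list. Of 26 lists, camera at the preset correlation called 8 for CpG and 10 for Poly(I:C), beside 13 and 15 for the responses by IFNAR. With an estimated correlation it called 0 in each, and fry called 1 and 0 by RelB and 3 and 5 by IFNAR. The gene calls by RelB were 71 for CpG (39 up, 32 down) and 16 for Poly(I:C) (6 up, 10 down). They were 12 and 5 without a filter and 0 and 0 with plain eBayes, where quantile normalisation gave 39 for CpG and voom 53 for Poly(I:C). Without the 2 shallowest libraries the Poly(I:C) count was 69, with 13 genes in common. Median-ratio scaling gave 23 up and 36 down for CpG and 4 up and 11 down for Poly(I:C).

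**Figure D3:**
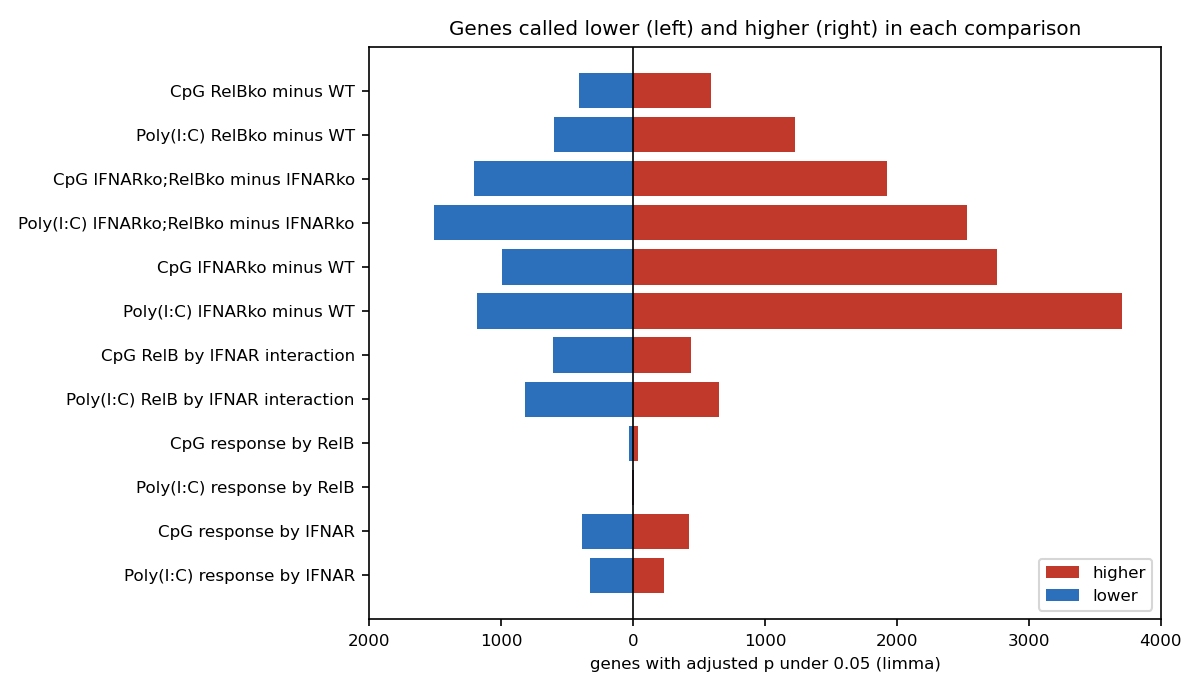
Number of genes called lower (left, blue) and higher (right, red) at an adjusted p under 0.05 by limma in each comparison. The RelB calls for the response (71 and 16) are few beside the IFNAR calls (812 and 564).

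Loss of RelB with IFNAR intact was read from RelBko and WT cells after CpG. Besides the sex-linked genes, the largest falls were Slc4a8, a sodium bicarbonate transporter (chromosome 15, 100761747 to 100823968; -3.61 ± 0.19, adjusted p 2e-08), and Apoe, the lipid carrier apolipoprotein E (chromosome 7, 19696109 to 19699188; -2.91 ± 0.20, adjusted p 3.6e-07). Slc4a8 was 29.2 CPM in WT control cells and 2.04 CPM in RelBko control cells, and Apoe was 29.7 and 2.11 CPM. The cytochrome Cyp1b1 fell by 2.73 ± 0.31, the chaperone clusterin (Clu) by 2.39 ± 0.15 and fibronectin (Fn1) by 2.12 ± 0.14. The lysophospholipase Enpp2 rose by 2.83 ± 0.22 (adjusted p 1.7e-06), Crxos by 3.29 ± 0.21, the Cdc42 exchange factor Fgd2 by 2.15 ± 0.20 and the CD8 chain Cd8b1 by 1.91 ± 0.18. Il12b (0.92 ± 0.63, adjusted p 0.47), Il6 (0.34), Tnf (-0.05 ± 0.16) and Nfkb2 (-0.04) were not called, and Ccr7 rose by 0.37 ± 0.11 (adjusted p 0.049). Apoe and Crxos lie within 5 Mb of Relb.

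Macrophage and monocyte markers fell in 12 of 22 cases and rose in 1 (13 and 1 adjusted over the list alone), among them Apoe, the phagocyte glycoprotein Gpnmb (-1.54 ± 0.16) and the lipid receptor Trem2 (-0.65 ± 0.09). The camera adjusted p was 2.9e-13, and the adjusted p = 0.016 with an estimated correlation. WT stood apart from all 3 other genotypes in these markers: after CpG their summed level was 5344 to 5906 CPM in WT, 2653 to 2937 CPM in RelBko, 2170 to 2390 CPM in IFNARko, which has RelB, and 2649 to 3046 CPM in the double knockout. In the double knockout against IFNARko 8 of 22 fell and 4 rose (the same counts adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Glycolysis and hypoxia genes fell in 9 of 23 cases (14 adjusted over the list alone) and none rose, led by the glycolytic activator Pfkfb3 (-1.20 ± 0.11) and Hif1a (-0.53 ± 0.09), with a camera adjusted p of 2.1e-09 and an adjusted p = 0.21 with an estimated correlation. Of 13 nitric oxide, arginine and itaconate genes 4 fell and none rose (4 adjusted over the list alone; adjusted p = 0.095 with an estimated correlation), all of them markers of alternatively activated macrophages: Retnla (-1.19 ± 0.09), Chil3 (-0.77 ± 0.07), Mrc1 (-1.46 ± 0.20) and Arg1 (-0.62 ± 0.12). Both of these lists were also lower in IFNARko than in WT over the stimulated libraries, with medians of -0.25 and -0.87 beside -0.33 and -0.48 in RelBko against WT. NF-kB genes rose in 5 of 27 cases and none fell, including Map3k14, the NIK kinase of the alternative NF-kB pathway (1.23 ± 0.16), and Map3k8 (0.66 ± 0.14), with the same counts adjusted over the list alone and a camera adjusted p of 0.25. Dendritic cell maturation genes moved both ways, with 9 of 37 up, as for Socs2 (0.94 ± 0.10), and 5 down, as for Cd63 (-0.95 ± 0.08; 14 up and 5 down adjusted over the list alone, camera adjusted p 0.64). Of 71 interferon-stimulated genes 1 rose (Ms4a4c, 1.00 ± 0.27, adjusted p 0.041) and none fell, and 0 were called adjusted over the list alone. None of 17 GBP and IRG genes was called by limma, with 0 at an unadjusted p under 0.05 and 0 by voom.

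Limma called 998 genes (589 up, 409 down), and median-ratio scaling gave 406 up and 595 down. The count was 188 without the 3 h libraries, 1932 with the control libraries added, 2232 with the WT and RelBko libraries alone and 1585 without the libraries of lowest depth. Of the 998 genes 97.8% had the same sign in the control libraries, against 69.9% of the genes not called, and no gene was called when each genotype was set against its own control library (155 at an unadjusted p under 0.05 by limma; voom was not run on that design).

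After Poly(I:C), Slc4a8 (-3.90 ± 0.17, adjusted p 6.2e-09), Apoe (-2.89 ± 0.24), Clu (-2.56 ± 0.20) and Cyp1b1 (-2.27 ± 0.34) again fell in RelBko. Lrrc16b rose by 2.71 ± 0.19, the collagen Col27a1 by 2.18 ± 0.20, Fgd2 by 2.16 ± 0.13, Cd8b1 by 2.04 ± 0.15 and Enpp2 by 1.96 ± 0.23. Nfkb2 fell by 0.27 ± 0.09 (adjusted p 0.048), and Il12b, Il6, Tnf, Cxcl10 and Ccr7 were not called. Of 23 glycolysis and hypoxia genes 11 fell and none rose (13 adjusted over the list alone; camera adjusted p 3.4e-10, adjusted p = 0.12 with an estimated correlation), as for Pfkfb3 (-1.17 ± 0.12) and Vegfa (-0.53 ± 0.08). Macrophage and monocyte markers fell in 7 of 21 cases and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). WT again stood apart, with a summed level at 8 h of 7528 CPM against 4847 CPM in RelBko, 3904 CPM in IFNARko and 4427 CPM in the double knockout, and in the double knockout against IFNARko 8 of 21 fell and 2 rose (9 and 3 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). Dendritic cell maturation genes rose in 12 of 37 cases, as for the chemokine Ccl22 (0.89 ± 0.09), and fell in 9 (13 up and 12 down adjusted over the list alone; camera adjusted p 0.23). None of 71 interferon-stimulated genes was called by limma (2 at an unadjusted p under 0.05, 0 by voom), nor was any of 17 GBP and IRG genes (0 and 0).

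Limma called 1827 genes (1230 up, 597 down), and median-ratio scaling gave 642 up and 903 down. The count was 346 without the 3 h libraries, 1082 without the 8 h libraries, 3066 with the control libraries added, 2933 with WT and RelBko alone and 0 against each genotype's own control (369 at an unadjusted p under 0.05 by limma). Of the genes tested after both stimuli, 463 rose and 297 fell after each, and 0 were called in opposite directions. Independent lists would share 58.7 and 19.7. The lists are not independent, since both compare RelBko with WT. Of the CpG and Poly(I:C) calls, 97.8% and 95.5% had the same sign in the control libraries. A lasting difference between the genotypes or their cultures would give this sharing too. The RelB effect was not called as different between stimuli for any of 12897 genes by limma (304 at an unadjusted p under 0.05, 0 by voom), with a median SE of 0.138 per gene for that difference.

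Loss of RelB without IFNAR was read from the double knockout and IFNARko. After CpG the lymphocyte proteases Gzma (-4.76 ± 0.10, adjusted p 2.2e-13), Gzmb (-3.74 ± 0.11) and Gzmc (-3.68 ± 0.14) fell, with Gzma at 341.5 CPM in IFNARko control cells and 10.2 CPM in double knockout control cells. The interferon-inducible GTPases Iigp1 (-4.06 ± 0.42) and Gbp4 (-3.54 ± 0.46) and the granulocyte protein S100a9 (-3.63 ± 0.24) also fell. The resistin-like gene Retnlg rose by 4.70 ± 0.28, Enpp2 by 4.21 ± 0.22, the eosinophil receptor Ccr3 by 3.66 ± 0.21 and the collagen crosslinker Lox by 2.90 ± 0.56. Tnf fell by 1.19 ± 0.16 (adjusted p 0.00033), Cxcl10 by 2.30 ± 0.47 and Nfkb2 by 0.49, and Ccr7 rose by 0.49. After Poly(I:C), Gzma (-4.77 ± 0.18), S100a9 (-3.86 ± 0.15) and Iigp1 (-3.64 ± 0.49) fell, Retnlg rose by 5.01 ± 0.27, and Il12b fell by 1.52 (adjusted p 0.0022).

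T and NK cell markers fell in 18 of 21 cases after CpG and 19 of 21 after Poly(I:C), where 1 rose (18 down and 1 up, and 19 down and 1 up, adjusted over the list alone). The camera adjusted p was 2.5e-23 and 5.6e-22, and the adjusted p = 0.11 and 0.12 with an estimated correlation. Their summed level was 1345 CPM in IFNARko control cells, against 288.8 CPM in WT, 275.4 CPM in RelBko and 156.7 CPM in double knockout control cells. GBP and IRG genes fell in 10 and 12 of 17 cases and none rose (13 and 14 adjusted over the list alone), with Gbp5 falling by 2.64 ± 0.23 and 2.59 ± 0.21, and the camera adjusted p was 2.1e-12 and 7.7e-11 (adjusted p = 0.23 and 0.26 with an estimated correlation). MHC class I genes fell in 17 of 20 cases after each stimulus and none rose (17 and 17 adjusted over the list alone; adjusted p = 0.24 and 0.29 with an estimated correlation), as for H2-Q7 (-1.47 ± 0.09 after CpG). MHC class II genes fell in 10 of 14 cases after each stimulus and rose in 0 and 1 (10 down, and 11 down and 1 up, adjusted over the list alone), with H2-Eb1 at -0.78 ± 0.12 and -0.81 ± 0.08 and an adjusted p = 0.21 and 0.26 with an estimated correlation. Interferon-stimulated genes fell in 8 and 7 of 71 cases and none rose (3 and 5 adjusted over the list alone; adjusted p = 0.67 with an estimated correlation in both). Voom called 12 lower and 0 higher after CpG and 16 lower and 1 higher after Poly(I:C). The small calls hide a broad shift: only 2 of the 71 were higher over the stimulated libraries (median -0.63). In control cells 4 were higher (median -0.53). Stromal markers rose in 8 of 10 cases after each stimulus and none fell (8 adjusted over the list alone; adjusted p = 0.11 and 0.14 with an estimated correlation), with the collagen Col1a1 up by 3.45 ± 0.23 after CpG, from 0.257 CPM in IFNARko to 7.01 CPM in double knockout control cells.

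Limma called 3132 genes after CpG (1926 up, 1206 down) and 4036 after Poly(I:C) (2530 up, 1506 down). Median-ratio scaling moved the median of all genes by -0.11 after CpG and gave 1082 up and 1615 down, and 1457 up and 1997 down after Poly(I:C). Without the 3 h libraries the counts were 956 and 1548, without the 8 h libraries the Poly(I:C) count was 2635, and against each genotype's own control they were 0 and 0 (103 and 150 at an unadjusted p under 0.05 by limma). Of the calls 98.1% and 98.5% had the same sign in the control libraries, against 73.7% of the genes not called after each stimulus. Between the IFNAR backgrounds, which share no library, 277 genes rose and 176 fell in both RelB comparisons after CpG (91.5 and 39.8 by chance), and 91 were called in opposite directions (121 by chance). After Poly(I:C) the counts were 594 up, 306 down and 148 opposite (248, 71.6 and 268 by chance).

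**Figure D4:**
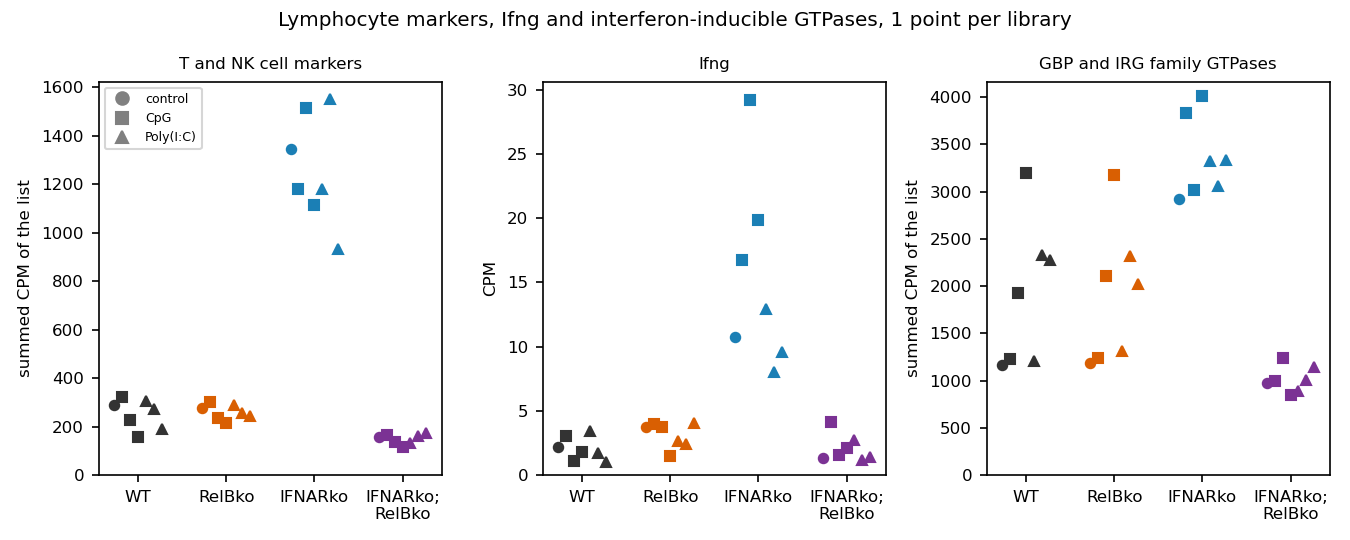
Summed CPM of T and NK cell markers (left), CPM of Ifng (middle) and summed CPM of GBP and IRG genes (right), 1 point per library, grouped by genotype with the stimulus as the symbol. IFNARko libraries held 930.9 to 1551 CPM of T and NK cell markers, above every library of the other 3 genotypes.

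Whether the RelB effect differed between IFNAR backgrounds was tested as an interaction. The RelB effect without IFNAR less that with IFNAR was -4.47 ± 0.14 for Gzma after CpG (adjusted p 1.4e-11) and -3.92 ± 0.14 for Gzmc after Poly(I:C). The collagenase gene Mmp8 (3.95 ± 0.23), Spint1, a protease inhibitor (3.37 ± 0.25), and Clu (2.88 ± 0.22) had higher interaction values after CpG, as did Spint1 (3.34 ± 0.21) and Igfbp4 (2.69 ± 0.12) after Poly(I:C). Tnf was lower after CpG (-1.14, adjusted p 0.0098), and Il12b (-1.77, adjusted p 0.015) and Nfkb2 (-0.44) after Poly(I:C). T and NK cell markers were called lower in 17 and 18 of 21 cases, GBP and IRG genes in 8 and 7 of 17, and MHC class I genes in 11 and 13 of 20, with none higher (18 and 19, 10 and 11, and 18 and 19 adjusted over the list alone). Their adjusted p = 0.10 and 0.12, 0.25 and 0.26, and 0.21 and 0.29 with an estimated correlation. Limma called 1051 genes after CpG (442 up, 609 down) and 1471 after Poly(I:C) (650 up, 821 down). Without the 3 h libraries the counts were 248 and 333, and without the 1 h libraries the CpG count was 678. With the control libraries added they were 1921 and 2452, and against own controls 0 and 0 (79 and 142 at an unadjusted p under 0.05 by limma). Sex-linked transcripts differ in the same pattern as the interaction, and 40 of the CpG calls and 56 of the Poly(I:C) calls lie on chromosomes X or Y. Among all genes tested, 369 of 12392 and 375 of 12552 lie there.

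Loss of IFNAR with RelB intact was read from IFNARko and WT. After CpG the T cell gene Cd8b1 rose by 3.44 ± 0.18 (adjusted p 6e-09), the transcription factor Epas1 by 2.96 ± 0.16, interferon gamma (Ifng) by 2.95 ± 0.31 and the NK cell granule gene Nkg7 by 2.89 ± 0.17. Cyp1b1 fell by 4.68 ± 0.31, the collagenases Mmp13 by 4.19 ± 0.50 and Mmp8 by 3.88 ± 0.16, and the interferon-stimulated genes Irf7 by 3.75 ± 1.00 and Oas2 by 3.73 ± 0.76. After Poly(I:C) the cell cycle genes Aspm (3.28 ± 0.36) and Cenpf (3.09 ± 0.25) and the GTPase Gbp5 (3.12 ± 0.21) rose, and the chemokine Cxcl3 (-4.51 ± 0.58), Oas1g (-4.07 ± 0.54) and Rsad2 (-3.73 ± 1.06, adjusted p 0.034) fell. Tnf fell by 0.55 after CpG, and Nfkb2 rose by 0.36 after CpG and 0.26 after Poly(I:C).

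Proliferation genes rose in 30 of 32 cases after CpG and 31 after Poly(I:C) and none fell (30 and 31 adjusted over the list alone), with Top2a, the topoisomerase of dividing cells, up by 2.68 ± 0.14 after CpG. The camera adjusted p was 4.1e-16 and 6.8e-12 (adjusted p = 0.21 and 0.36 with an estimated correlation). T and NK cell markers rose in 18 and 20 of 21 cases and none fell (19 and 21 adjusted over the list alone; adjusted p = 0.18 and 0.22 with an estimated correlation), and mast cell, basophil and eosinophil markers in 11 and 12 of 15, as for Mcpt8 (2.73 ± 0.23 after CpG), with the same counts adjusted over the list alone and an adjusted p = 0.21 and 0.38 with an estimated correlation. Macrophage and monocyte markers fell in 13 of 22 cases after CpG and 12 of 21 after Poly(I:C) and rose in 2 and 1 (15 down and 2 up, and 13 down and 1 up, adjusted over the list alone), as for Csf1r (-1.18 ± 0.08) and Gpnmb (-2.84 ± 0.16) after CpG. Their adjusted p = 0.016 after CpG and 0.11 after Poly(I:C) with an estimated correlation. Interferon-stimulated genes fell in 12 and 22 of 71 cases and rose in 2 and 1 (11 down and 2 up, and 19 down and 1 up, adjusted over the list alone; camera adjusted p 1.1e-14 and 6.8e-17, adjusted p = 0.52 and 0.50 with an estimated correlation), and voom called 39 and 46 lower. These averages include the 1 h libraries. GBP and IRG genes rose in 5 and 7 of 17 cases and none fell, with the same counts adjusted over the list alone, among them Gbp2 (1.29 ± 0.15 after CpG), and the camera adjusted p was 0.23 and 0.14. The other pair that differs in IFNAR is the double knockout against RelBko. Over its stimulated libraries 2 of 21 T and NK cell markers (median -0.46) and 0 of 17 GBP and IRG genes (median -0.70) were higher. Proliferation genes (31 of 32, median 1.87) and mast cell, basophil and eosinophil markers (13 of 16, median 1.41) were higher in that pair too. Limma called 3754 genes after CpG (2759 up, 995 down) and 4888 after Poly(I:C) (3707 up, 1181 down), and 1411 and 2190 without the 3 h libraries. Against own controls they were 0 and 0 (165 and 327 at an unadjusted p under 0.05 by limma). Median-ratio scaling moved the median by -0.14 in both and gave 1584 up and 1548 down, and 2028 up and 1951 down, so the excess of rises depends on the scaling.

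The RelB effect averaged over IFNAR backgrounds and stimuli was then tested at each time. Nitric oxide, arginine and itaconate genes fell in 7, 9 and 8 of 13 cases at 1, 3 and 8 h and none rose (9, 9 and 9 adjusted over the list alone), with an adjusted p = 0.0077, 0.0034 and 0.0039 with an estimated correlation. Glycolysis and hypoxia genes fell in 14, 17 and 19 of 23 cases and rose in 1, 0 and 0 (15, 18 and 21 down adjusted over the list alone; adjusted p = 0.037, 0.016 and 0.011 with an estimated correlation). MHC class II genes fell in 9 of 14 cases at each time and rose in 1, 0 and 3 (the same counts adjusted over the list alone; adjusted p = 0.019, 0.011 and 0.046 with an estimated correlation). T and NK cell markers fell in 17 of 21 cases and rose in 1 at each time (17, 18 and 17 down adjusted over the list alone; adjusted p = 3.6e-04, 3.6e-04 and 0.0016 with an estimated correlation), and their summed level in IFNARko was 930.9 to 1551 CPM. Both of these falls lay between the double knockout and IFNARko, where 1 of 14 MHC class II genes and 2 of 21 T and NK cell markers were higher over the stimulated libraries (medians -0.49 and -2.54). In RelBko against WT 11 of 14 and 17 of 21 were higher (medians 0.12 and 0.17). Proliferation genes rose in 3, 21 and 28 of 32 cases and none fell (1, 22 and 28 adjusted over the list alone), with an adjusted p = 0.17 at 3 h and 0.078 at 8 h with an estimated correlation. Limma called 3442 genes at 1 h (2107 up, 1335 down), 4599 at 3 h (3126 up, 1473 down) and 5220 at 8 h (3628 up, 1592 down). The RelBko and WT libraries alone gave 1470, 2166 and 2509 calls. Median-ratio scaling moved the median by -0.11 at 8 h and gave 1245 up and 1792 down, 1463 up and 2131 down, and 1824 up and 2479 down.

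In control cells, limma called 877 genes for the RelB effect (452 up, 425 down), and median-ratio scaling gave 311 up and 582 down. Macrophage and monocyte markers fell in 6 of 23 cases (adjusted p = 0.006 with an estimated correlation), nitric oxide, arginine and itaconate genes in 4 of 13 (adjusted p = 0.011 with an estimated correlation) and T and NK cell markers in 14 of 21 (adjusted p = 0.022 with an estimated correlation), and no member of these lists rose. Adjusted over the list alone the falls were 6, 4 and 17, with 1 rise among the T and NK cell markers. The summed level of the macrophage and monocyte markers was 5834 CPM in WT, 3103 in RelBko, 2537 in IFNARko and 2629 in double knockout control cells. In RelBko against WT 3 of 23 were higher (median -0.46), and in the double knockout against IFNARko 9 of 23 (median -0.22). Of the 13 nitric oxide, arginine and itaconate genes 6 were higher in RelBko against WT (median -0.08). In the double knockout against IFNARko 3 of them were higher (median -0.41), so most of that fall lay without IFNAR. In RelBko against WT control cells 10 of the 21 T and NK cell markers were higher, and in the double knockout against IFNARko 1 was. Their summed level was 1345 CPM in IFNARko, 288.8 in WT, 275.4 in RelBko and 156.7 in double knockout control cells. Each genotype had 1 control library, which was taken to vary like the stimulated libraries.

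Induced genes were compared by whether their induction needed IFNAR. Of 231 IFNAR-dependent genes classed in Poly(I:C) libraries, 1 rose and 24 fell in RelBko after CpG, with a median of -0.03 against 0.07 for other genes and a camera adjusted p of 3.8e-06. Of 256 such genes classed in CpG libraries, 1 rose and 30 fell after Poly(I:C), with a median of -0.14 against 0.09 and a camera adjusted p of 1.8e-09. For both the adjusted p = 0.72 with an estimated correlation. IFNAR-independent genes were not called as a class: 43 of 300 rose and 22 fell after CpG (median 0.15, camera adjusted p 0.37), and 98 of 419 rose and 34 fell after Poly(I:C) (median 0.15, camera adjusted p 0.37). Without IFNAR, in the double knockout against IFNARko, the dependent classes had medians of -0.21 after CpG (22 up, 26 down, camera adjusted p 8.5e-05) and -0.17 after Poly(I:C) (34 up, 29 down, camera adjusted p 0.0073), with an adjusted p = 0.72 and 0.79 with an estimated correlation. Camera called the independent classes lower there as well, with medians of 0.02 after CpG (47 up, 65 down, camera adjusted p 0.0066) and -0.02 after Poly(I:C) (93 up, 106 down, camera adjusted p 0.0064), and an adjusted p = 0.72 with an estimated correlation for both. Class and test shared no library, but classes were made from genes high in WT, and genotype differences persisted over conditions. This favours values below WT in RelBko. The independent classes were also chosen for IFNARko values close to or above WT, which favours double knockout values below IFNARko. Their lower values in that comparison therefore cannot be told apart from the choice of genes. The dependent classes were chosen for low IFNARko values, which favours the opposite direction there. With 4-fold limits camera at the preset correlation called both dependent classes lower than other genes. The class of 56 genes had 1 fall, no rise and a median of 0.052 against 0.069 for other genes after CpG (camera adjusted p 0.034). That of 68 genes had 2 falls, no rise and a median of -0.120 against 0.089 after Poly(I:C) (camera adjusted p 5.8e-04). For both the adjusted p = 0.79 with an estimated correlation. With these limits the independent classes held 9 and 73 genes, with medians of 0.54 and 0.26 and a camera adjusted p of 0.034 and 0.017, and the adjusted p = 0.79 with an estimated correlation for both.

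Genes near Relb were called more often than genes elsewhere. Among 80 tested genes within 5 Mb of Relb on chromosome 7, 13 were called with the same sign in both RelB comparisons after both stimuli (16.2%), against 313 of 11205 elsewhere (2.79%; odds ratio 6.75, Fisher's exact p 4.2e-07). They included Apoe, Crxos and Ceacam19. After CpG the odds ratio near Relb was 4.27 for RelBko against WT, 1.37 (95% interval 0.825 to 2.22) for the double knockout against IFNARko and 0.945 for IFNARko against WT, and with Poly(I:C) it was 3.68, 1.96 and 0.776. This window was chosen after the values were seen.

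**Figure D5:**
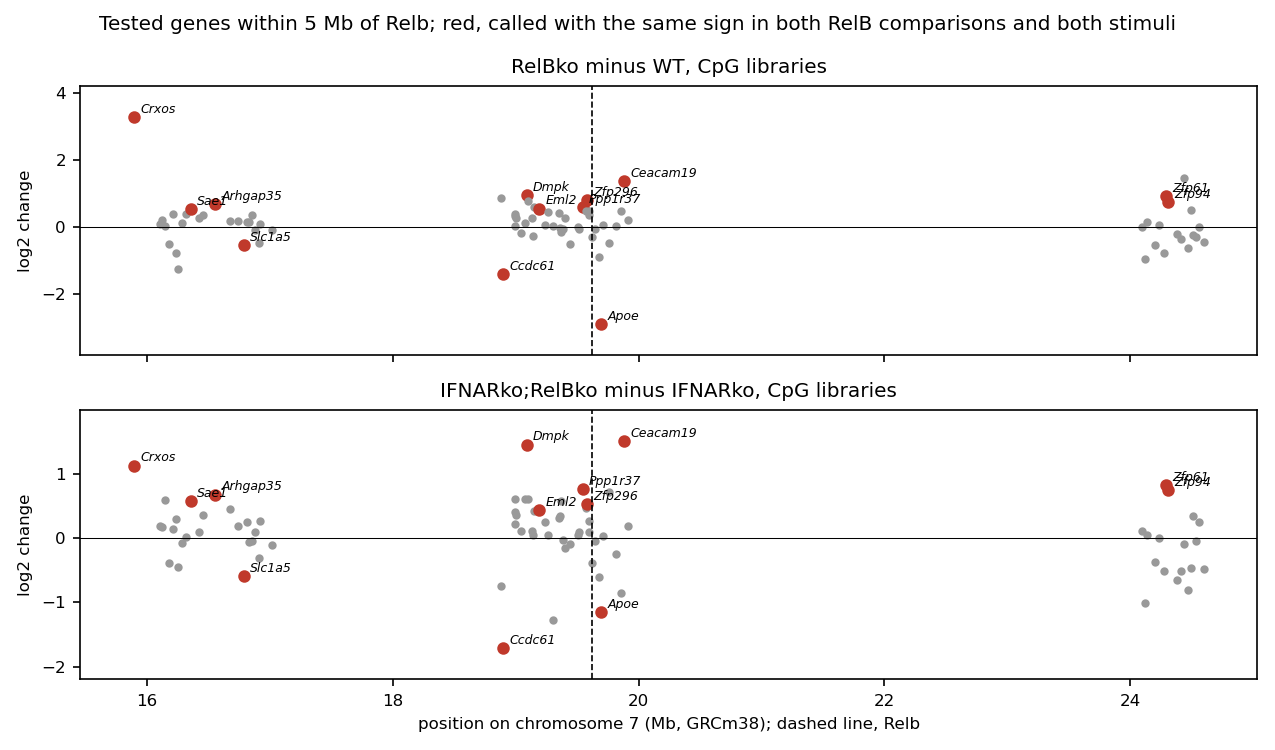
Log2 change after CpG of tested genes by position on chromosome 7 (Mb) within 5 Mb of Relb, for RelBko minus WT (top) and double knockout minus IFNARko (bottom), 1 point per gene, with the dashed line at Relb. Red marks the 13 genes called with the same sign in both comparisons after both stimuli.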

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

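All tests of explanations and of other splits in this part were chosen only after the results were seen.

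The WT CpG 8 h library held 42227938 reads, far above the other 6 WT libraries (the gap to the nearest was 0.853 of the range of all 7), and chance marks about 1 in 20 such groups. The RelB effect differed between IFNAR backgrounds for 1051 genes after CpG and 1471 after Poly(I:C), by the interaction test. The CpG response differed with RelB for 71 genes and with IFNAR for 812, and the Poly(I:C) response for 16 and 564, each by a test of the difference itself.

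GBP and IRG genes were lower in the double knockout than in IFNARko libraries, a contrast in which T and NK cell markers also fell. With median-ratio scaling 10 of the genes were still called lower after CpG and 12 after Poly(I:C). That scaling moved the median of all genes in this contrast by -0.107 and -0.096, so falls could hardly lose their call. The kept calls therefore decide little about scaling to a fixed read total. The shift shows only that the fixed total raised values in this contrast relative to median-ratio scaling. T and NK cells in the IFNARko cultures, which could release interferon gamma, a known inducer of these GTPases, remain a candidate explanation: the marker median was at least 2.00 log2 higher in the IFNARko control library than in each other control library, and without such a difference, in RelBko against WT, the GTPase median was 0.081 after CpG. The most abundant markers in IFNARko control cells were Gzmb at 371.8 CPM and Gzma at 341.5 CPM, Ifng was 8.03 to 29.2 CPM in IFNARko libraries and at most 4.14 CPM elsewhere, 19 of the 21 markers also reached 1 CPM in WT control cells and 0 sit in another list, and the labels name no sort that would remove such cells. Loss of RelB without IFNAR signalling cannot be told apart from it, because 1 culture or animal may stand behind each genotype, and the GTPase median was already -1.20 in unstimulated double knockout against IFNARko cells.

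WT and double knockout libraries carried Xist, and RelBko and IFNARko libraries carried Y-linked transcripts, which is consistent with female and male animals. Sex as the source of genes called in both RelB comparisons is argued against by direction: after CpG 277 rose and 176 fell in both, while 91 went in opposite directions, as a sex effect would require. For the interaction, sex and genotype cannot be told apart, since both follow the same contrast. Of the 1051 CpG calls 40 lie on chromosomes X or Y, beside 369 of the 12392 genes tested. Each genotype comparison taken alone has the same limit.

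Genes within 5 Mb of Relb were called with the same sign in both RelB comparisons and both stimuli more often than genes elsewhere (odds ratio 6.75, 95% interval 3.38 to 12.5), and 0 of 1212 other windows had as high a share. DNA around the targeted locus from another mouse strain is a candidate explanation that stays open: after CpG the odds ratio was 4.27 in RelBko against WT and 0.945 in IFNARko against WT, while in the double knockout against IFNARko it was 1.37 (0.825 to 2.22) after CpG, an interval that includes 1, and 1.96 (1.23 to 3.11) after Poly(I:C), an interval that does not. RelB protein acting on its neighbours cannot be told apart from it, since all 13 genes had the same sign in unstimulated cells and strain sequence was not used here. The fall of Apoe, a neighbour of Relb, may therefore not depend on RelB protein.

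Other splits of the samples were fitted for the counts. For the 6 genotype counts of 998, 3132 and 3754 (CpG) and 1827, 4036 and 4888 (Poly(I:C)), 10 splits of 6 libraries are too few for a share under 0.05, and the highest of the others was 0. Swapping control and stimulated libraries within genotypes gives 8 splits, which are also too few, for the responses at 1, 3 and 8 h of 64, 5574 and 6817 genes (CpG) and 42, 2991 and 5457 (Poly(I:C)), and the highest of the others was 0. The 4 genotypes can be paired in 3 ways, again too few, for the counts that follow. The interactions of 1051 and 1471 were the lowest of their 3 pairings (highest other 5834 and 6851). The RelB effect over both stimuli (3442, 4599 and 5220 at 1, 3 and 8 h) was reached by 2 of 3 pairings (highest other 5575, 6741 and 7621). Of the responses by genotype, 2 of 3 pairings gave at least the 71 and 16 by RelB (highest other 812 and 564), and the 812 and 564 by IFNAR were the highest (highest other 71 and 16). Each of these highest others above 71 was the pairing by IFNAR, which is the comparison of IFNAR-null with IFNAR-intact genotypes itself. These counts therefore reflect the larger number of differences along IFNAR genotype and are not separate evidence of a structure of the samples. For the difference of the RelB effect between stimuli the real count was 0, so all 100 splits gave as many, with 2587 at most. Schemes run earlier took the libraries of a genotype as independent and were set aside, because 1 culture or animal may stand behind each genotype. They gave as many calls in 3 and 1 of 100 splits for the interactions, 9, 7 and 3 of 100 for the RelB effect at 1, 3 and 8 h, 42 and 43 of 100 for responses by RelB and 24 and 30 by IFNAR, 2 and 2 of 35 for the 1 h responses and 1 of 35 for each of the 4 later ones.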

How the results depend on the processing

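The voom fits, the removal of shallow libraries, of sex-linked genes and of genes near the targeted loci, the fits against own controls and the fits of responses by RelB and IFNAR were tests chosen after the results were seen. Of 315 comparisons of a result with an alternative, 255 stayed within 1.5 times the reported count or kept the reported call, and of 5207 comparisons for named genes 5158 kept their direction and 4829 also their side of the threshold. The pseudocount, the stricter filter and the removal of sex-linked genes or of genes near Relb and Ifnar1 left every count they were run on within 1.5 times. For the counts below the cause was not tested, except where fewer or more libraries were used. A count-based method with its own size factors was not run on the recovered reads. The CpG response by IFNAR could not be estimated without the 2 shallowest libraries, both of CpG 8 h. These held 3269933 and 3814916 reads, where 1 read is a large part of a value near 1 CPM.

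Without a filter on low values the response calls were 12 (CpG) and 5 (Poly(I:C)) by RelB and 513 and 356 by IFNAR. With eBayes without trend and robust they were 0 and 0 by RelB and 341 and 245 by IFNAR, and the Poly(I:C) 1 h calls were 0. Median-ratio scaling gave 7 Poly(I:C) 1 h calls, and quantile normalisation gave 26, and 39 for the CpG response by RelB. Voom gave 19 Poly(I:C) 1 h calls and 53 for the Poly(I:C) response by RelB. With the control libraries as a further time level, RelBko against WT gave 1932 (CpG) and 3066 (Poly(I:C)) and the interaction 1921 and 2452. With the libraries of the compared genotypes alone, RelBko against WT gave 2232 and 2933. Without the 2 shallowest libraries it gave 1585 after CpG, the CpG 1 h response 109, and the Poly(I:C) response 69 by RelB and 871 by IFNAR. With IFNAR intact alone, the RelB effect over both stimuli gave 1470, 2166 and 2509 at 1, 3 and 8 h. Set against own controls, all 8 genotype counts were 0 by limma (79 to 369 at an unadjusted p under 0.05, and voom was not run on that design). That fit has 1 control library per genotype and counts genotype-by-time change as spread. Its counts of 0 therefore cannot show that genotype effects were the same without stimulation.

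Leaving out each time in turn gave 188 to 782 calls for RelBko against WT, 956 to 2389 for the double knockout against IFNARko, 1411 to 3328 for IFNARko against WT and 248 to 852 for the interaction after CpG. With Poly(I:C) it gave 346 to 1422, 1548 to 3329, 2190 to 4459 and 333 to 1059. The lowest value of each came without the 3 h libraries. Leaving out each genotype in turn gave 30 to 81 calls at CpG 1 h, 0 to 25 at Poly(I:C) 1 h, 1184 to 2549 at Poly(I:C) 3 h and 3442 to 5130 at Poly(I:C) 8 h. The lowest of these 4 ranges came without RelBko.

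Over the 8 genotype and interaction comparisons within a stimulus, camera called 86 sets with the preset and 2 with an estimated correlation, and fry called 91. In the other comparisons an estimated correlation called 5, 4 and 4 sets for CpG at 1, 3 and 8 h, 8, 6 and 5 for the RelB effect over both stimuli and 3 in control cells. For the IFNAR-dependent classes camera with an estimated correlation gave an adjusted p of 0.72 after CpG and 0.72 after Poly(I:C). With 4-fold limits the IFNAR-independent classes were called with the preset correlation, with medians of 0.537 (9 genes) and 0.259 (73 genes), while an estimated correlation gave an adjusted p of 0.79 for each. With the class made in the same stimulus, the Poly(I:C) independent class had a median of 0.125 while camera gave the opposite direction from the reported test, without a call in either.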

Other observations

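No test in this part was chosen after the results were seen.

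Chemokine genes rose in 2, 14 and 14 of 19 cases after CpG at 1, 3 and 8 h and fell in 0, 1 and 3 (5, 14 and 14 up and 0, 1 and 3 down adjusted over the list alone), with Ccl3, which draws monocytes, up by 3.69 ± 0.16 at 8 h and Ccl5 by 1.76 ± 0.11. With an estimated correlation the adjusted p values of the list were 0.049, 0.038 and 0.056. Cholesterol synthesis and uptake genes fell in 13 of 23 cases at 8 h of CpG and 14 at 8 h of Poly(I:C) and rose in 2 and 2 (the same counts adjusted over the list alone), with a camera adjusted p of 0.19 and 0.0071 and an adjusted p = 0.94 and 0.83 with an estimated correlation. Ribosomal protein genes fell in 32 of 36 cases after CpG and 30 after Poly(I:C) at 8 h (33 and 33 adjusted over the list alone; adjusted p = 0.94 and 0.83 with an estimated correlation), as for Rps16 (-0.67 ± 0.11 and -0.43 ± 0.06). They rose in 23 and 33 of 36 cases in the double knockout against IFNARko (31 and 35 adjusted over the list alone; adjusted p = 0.73 and 0.60 with an estimated correlation). All 7 mitochondrially encoded genes rose at 8 h of Poly(I:C) (7 adjusted over the list alone; adjusted p = 0.74 with an estimated correlation), as for mt-Nd5 (0.69 ± 0.09), a subunit of respiratory complex I. Nucleic acid sensing genes rose in 12 of 28 cases at 8 h of Poly(I:C) and none fell (12 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation).

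Markers of other cell types differed between genotypes. B cell markers fell in 5 of 8 cases in the double knockout against IFNARko after CpG and 6 of 9 after Poly(I:C), where 1 rose (5 and 8 down adjusted over the list alone; adjusted p = 0.21 and 0.13 with an estimated correlation), as for Igkc (-1.33 ± 0.19 after Poly(I:C)). Markers of type 1 conventional dendritic cells rose in 6 of 10 cases in IFNARko against WT after CpG and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p 0.21). Neutrophil and granule markers moved both ways in RelBko against WT after CpG, with 6 of 18 up and 3 down (8 and 3 adjusted over the list alone; camera adjusted p 0.20). Markers of type 2 and GM-CSF dendritic cells had 2 of 15 up and 1 down in that comparison (4 and 3 adjusted over the list alone; camera adjusted p 0.73), plasmacytoid markers 1 of 10 up (1 adjusted over the list alone; camera adjusted p 0.32) and reference genes 1 of 19 up (1 adjusted over the list alone; camera adjusted p 0.79). The summed level of mast cell, basophil and eosinophil markers was 149 CPM in IFNARko and 154 CPM in double knockout control cells, against 55.6 CPM in WT and 46.0 CPM in RelBko.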
